A study of Mus musculus with 6 samples.

How the data were processed

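Polyadenylated RNA was measured by RNA-seq in 6 libraries of 4T1, a mouse mammary carcinoma line. Per the series' design text, the cells had been taken from lesions that formed after surgery in mice given axitinib, an inhibitor of VEGF receptor kinases, at 100 mg/kg/day, and were then kept in culture with 0.5 µM axitinib. The cells were stained with C12FDG, a substrate that turns fluorescent when β-galactosidase cleaves it, and sorted into a high-signal fraction (SM positive, 3 libraries) and a low-signal fraction (SM negative, 3 libraries). Per the labels' protocols, RNA was treated with DNase on the column and libraries were made with a stranded mRNA kit.

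The deposited values are expected counts per gene, which need not be whole numbers. Per the submitters' processing notes, the tools were FastQC 0.11.5, STAR 2.6.0a and RSEM 1.3.1 with the GRCm38 mouse genome build; the notes give them no order or role. The annotation release and the strand setting used for counting are not given in the sources used here, so reads of a gene and of its antisense partner may not be separated. The table holds 53465 genes, and 99.6% of their identifiers matched the GENCODE M21 annotation (GRCm38) once version numbers were ignored. Symbols and coordinates (1-based) come from that match, and at most 0.026% of any library's counts lay in identifiers that did not match.

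Expected counts were rounded to whole numbers before any test. Between 13.5% and 14.4% of the values of a library were not whole as deposited. Total counts were 25302168, 18733801 and 21000844 for SM negative replicates 1, 2 and 3, and 26533528, 21622938 and 19691379 for SM positive replicates 1, 2 and 3. Where a gene had no count, the upper limit was set at 3 counts, which is 0.113 to 0.16 CPM (the count scaled to the usual common library total) depending on the library. Such limits cover counting error only, because PCR copies are not independent molecules. No 2 libraries agreed within sampling noise: the chi-square per gene was between 6.35 and 18.3 over all pairs.

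Genes were filtered with edgeR's filterByExpr, which left 14038, and scaled by TMM. Differences between fractions were tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, robust fit) with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are SM positive over SM negative, and CPM values are TMM-scaled. Each adjusted p for a gene comes from this test unless another tool is named. Shares of counts per library were compared with an exact 2-sided permutation test, whose smallest possible p with 3 against 3 libraries is 0.1.

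Before the data were examined, 29 gene lists holding 1173 genes were written from general knowledge, as were the main test, the other settings and the rule for named genes. The 26 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log CPM with a prior count of 2 and a preset correlation between genes of 0.01. Camera compares a list with the other genes. It was run again with the correlation estimated from the data, and fry, which does not compare a list with other genes, was run beside it. List tests were adjusted over the 26 lists.

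The rule for named genes had 4 parts. Among genes past the threshold with a mean of at least 5 CPM and no overlap between the fractions' libraries, it took the 10 with the greatest rise and the 10 with the greatest fall, leaving out predicted and clone-named genes. It also took Glb1, Cdkn1a, Cdkn2a, Cdkn2b, Lmnb1, Mki67 and Il6 whatever their values. From each list it took up to 2 members that rose and up to 2 that fell with the smallest p and a mean of at least 1 CPM. For each list of another cell type, it took the 2 members with the highest mean CPM. Genes named outside the rule are said to be chosen after their values were seen. The values of a few list members are not reported here.

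Nothing in the labels says what a replicate number marks, or that replicates came from separate cultures or sorts, so p-values measure the spread between these libraries, which may be technical. Whether the numbers pair the libraries was decided from the data, before any fits were compared. Deviations from the fraction means, correlated across genes, were 0.22, 0.28 and 0.196 between libraries with the same number and between -0.175 and -0.043 between libraries with different numbers. All 3 same-number values exceeded the minimum of 0.1 fixed in advance, so the numbers were taken to pair the libraries. The fit with the replicate number as a block was among the settings fixed in advance, and its values are printed beside a result where they change a call or a count by more than 1.5 times.

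Other alternatives were relative log expression (RLE) size factors, library totals with no further scaling, no filter, a filter of more than 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit without robust estimation, stricter thresholds, and leaving out each library in turn. DESeq2 gave no adjusted p for 1 gene, which was left without a call. Genes sharing sequence were found as the share of 31-base stretches of a gene's transcripts that occur in another gene.

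The steps were tested on simulated data with 14038 genes, drawn with the means and library sizes of these 6 libraries. Every simulated gene had the spread between libraries (dispersion) of the unblocked fit, 0.00637, and the pair effect was added to it. That dispersion already held the variation between pairs, and the blocked fit's own was 0.00182. The recoveries with a pair effect are thus not those of the real fits. Without a simulated pair effect, the test recovered 30% of genes changed 1.25-fold, 80% of those changed 1.5-fold and all of those changed 2-fold or 4-fold, and 3.73% of its calls were false. With a simulated pair effect, the unblocked test recovered 4% at 1.25-fold and 54% at 1.5-fold, and the blocked test 16% and 84%.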

Results

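Gene expression was compared between C12FDG-high (SM positive) and C12FDG-low (SM negative) cells sorted from a single axitinib-resistant population of 4T1 breast cancer cells. High β-galactosidase activity of this kind is commonly used to mark senescent cells, and the comparison asks which transcripts separate the fractions. There were 3 libraries in each fraction, with 18733801 to 26533528 counts per library. CPM values are given as mean ± SD over n = 3 libraries. The share of counts from mitochondrial transcripts was 1.73% ± 0.172 in SM positive and 1.70% ± 0.137 in SM negative libraries (exact permutation p = 0.9). The 59 ribosomal protein genes of the written list took 4.38% ± 0.0887 and 4.78% ± 0.284 (exact permutation p = 0.2). The 10 most abundant genes took 4.73% ± 0.0518 and 4.95% ± 0.0145 (exact permutation p = 0.1, the smallest this design allows).

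In SM positive cells, 9 of 63 interferon-response genes and 4 of 33 mesenchymal and matrix genes were higher, and none of either list was lower. Both lists were called higher by camera with a preset correlation between genes, but not with an estimated one (adjusted p = 0.68 and adjusted p = 0.295 with an estimated correlation). Single genes such as Inmt, Ogn, Inhbb, Vdr and Pdgfc were higher, and the laminin-332 chains Lama3 and Lamb3 and the cytokine Il24 were lower. Glb1, which encodes the lysosomal β-galactosidase, did not pass the test, and neither did Cdkn1a or Lmnb1. Of 14038 genes tested, 190 passed the threshold, 160 higher and 30 lower in SM positive cells, and 34 of these differed at least 2-fold. With the replicate number as a block, 1982 genes passed, 1196 higher and 786 lower, and these included all 190. In that fit 81 differed at least 2-fold, 30 higher and 51 lower, against 19 higher and 15 lower without the block. The median absolute log2 change was 0.52 among the 190 genes and 0.23 among the 1982. Principal component 1, with 27.9% of the variance, separated the fractions, and components 2 and 3, with 24.1% and 20.5%, separated libraries by replicate number.

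The number of genes depended on each library. Without SM negative replicate 1, 2 or 3 it was 43, 25 and 39, and without SM positive replicate 1, 2 or 3 it was 123, 117 and 48. Of the 33 named genes past the threshold, 19, 25, 20, 8, 7 and 17 lost the call in the same order, and none of the 33 changed direction. Inmt, Inhbb, Il24, Dynap, Ifi44 and Pdgfc stayed under an adjusted p of 0.05 in every one of these fits, while Trp53, Spata7, Wnt7a, Nrp1, Cdkn2c and Insig1 lost the call in all 6. These fits had no replicate block, although the numbers were taken to pair the libraries. In blocked fits chosen after the data were seen, leaving out pair 1, 2 or 3 gave 705, 1793 and 886 genes. With the block and all 6 libraries, Trp53, Spata7, Wnt7a, Nrp1, Cdkn2c and Insig1 passed at adjusted p = 0.00316 or less.

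**Figure D1:**
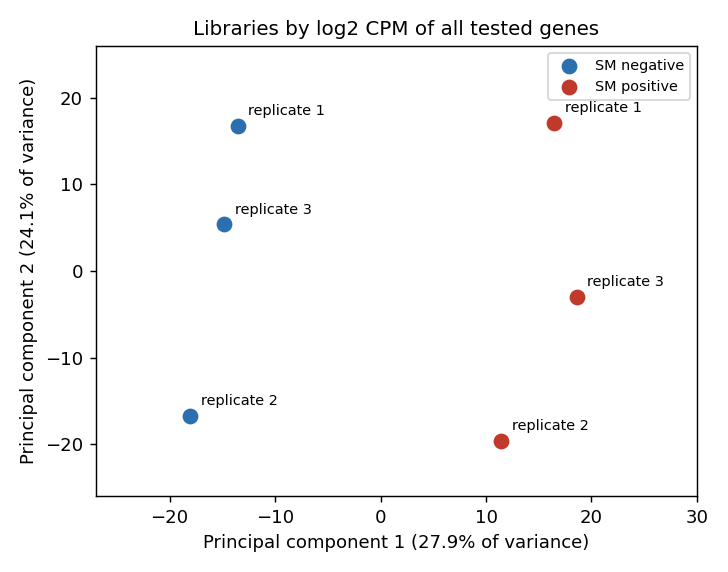
Libraries placed by principal component 1 (27.9% of variance, horizontal) and 2 (24.1%, vertical) of log2 CPM over all tested genes; each point is 1 library, coloured by fraction and marked with its replicate number. The fractions part along component 1, and libraries with the same replicate number lie at similar heights on component 2.

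The genes linked to the sort and to senescence showed small differences. Glb1 (ENSMUSG00000045594.10, chromosome 9, 114401076 to 114474898, plus strand) stood at 43.2 ± 2.18 CPM in SM positive and 40.8 ± 2.65 CPM in SM negative cells, a log2 change of 0.08 ± 0.073 (SE; adjusted p = 0.682). Tmppe overlaps it on the same strand. Cdkn1a, which encodes the cell cycle inhibitor p21, stood at 16.9 ± 1.03 and 19.0 ± 0.884 CPM (log2 change -0.16, adjusted p = 0.446). Lmnb1, a nuclear lamin that is often low in senescent cells, stood at 179.5 ± 15.5 and 183.8 ± 7.27 CPM (log2 change -0.03, adjusted p = 0.88). Mki67, a marker of cycling cells, stood at 427.8 ± 10.1 and 483.4 ± 19.8 CPM (log2 change -0.18, adjusted p = 0.169). With the replicate block, the Mki67 difference passed at adjusted p = 0.0042, and over the other alternatives its adjusted p reached 0.391. Cdkn2a and Cdkn2b, which encode p16 and p15, had 0 counts in all 6 libraries, which allows levels of up to 0.113 to 0.16 CPM. Il6 had 0 to 3 counts per library, so a difference was not detectable at this depth.

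Among the 160 genes that were higher in SM positive cells, 148 met the level and overlap conditions, and 145 of these carried a gene symbol. Inmt, an indolethylamine N-methyltransferase (ENSMUSG00000003477.5, chromosome 6, 55170626 to 55175043, minus strand), rose from 2.39 ± 0.65 to 8.45 ± 1.71 CPM, which is 3.55-fold (log2 change 1.83 ± 0.214 SE, adjusted p = 0.00489). Ogn, the small matrix proteoglycan osteoglycin (chromosome 13, 49608046 to 49624501, plus strand), rose from 5.35 ± 1.9 to 15.8 ± 3.56 CPM (log2 change 1.56 ± 0.248 SE, adjusted p = 0.0285). Ccn5, a secreted protein of the CCN family, rose 2.71-fold, the sugar-phosphate transporter gene Slc37a2 2.35-fold, and the olfactomedin-domain matrix gene Olfml2b 2.13-fold. Inhbb, the βB subunit of activins and inhibin B, rose from 7.65 ± 0.777 to 16.7 ± 1.47 CPM (log2 change 1.12 ± 0.111 SE, adjusted p = 0.002). Dock4, an activator of Rac and Rap GTPases, rose 2.03-fold. Slc43a2, an amino acid transporter, rose 1.99-fold, as did Vdr, the nuclear receptor for vitamin D (from 5.92 ± 0.788 to 11.8 ± 0.907 CPM, adjusted p = 0.00704). Ephb6, a kinase-inactive ephrin receptor, rose 1.93-fold.

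Among the 30 genes that were lower, 15 met the same conditions, and 13 of these carried a symbol. Lama3 (ENSMUSG00000024421.16, chromosome 18, 12333819 to 12583013, plus strand) fell from 18.9 ± 1.89 to 9.29 ± 1.57 CPM (log2 change -1.02 ± 0.129 SE, adjusted p = 0.00708), and Lamb3 from 39.1 ± 4.3 to 21.2 ± 5.13 CPM (log2 change -0.88 ± 0.157 SE, adjusted p = 0.0364). Their products are the α3 and β3 chains of laminin-332, a basement membrane protein of epithelia. Il24, a cytokine of the IL-10 family, fell from 17.7 ± 1.37 to 9.27 ± 0.587 CPM (log2 change -0.93 ± 0.0995 SE, adjusted p = 0.00239). Acsbg1, an acyl-CoA synthetase, was 1.66-fold lower, the membrane protein gene Dynap 1.6-fold, and Rgs16, a regulator of G protein signalling, 1.56-fold. Sag, the retinal arrestin gene, was 1.41-fold lower, and Spata7 and the Wnt ligand Wnt7a were each 1.33-fold lower. Trp53, which encodes the p53 tumour suppressor (chromosome 11, 69580359 to 69591873, plus strand), fell from 53.4 ± 3.72 to 41.8 ± 0.531 CPM (log2 change -0.36 ± 0.068 SE, adjusted p = 0.0349), and 10.1% of its 31-base stretches also occur in other genes. In fits without the replicate block, the Trp53 call ended with each single library left out (adjusted p from 0.0677 to 0.148) and with limma-voom (0.0509). With the block and no library left out, the Trp53 adjusted p was 6.99e-05. Genes annotated on the opposite strand overlap Slc37a2, Slc43a2, Lama3, Rgs16, Cdkn1a, Car9, Pdgfc and Ahr, and the strand setting of the counting is not known, so their levels may include antisense reads.

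**Figure D2:**
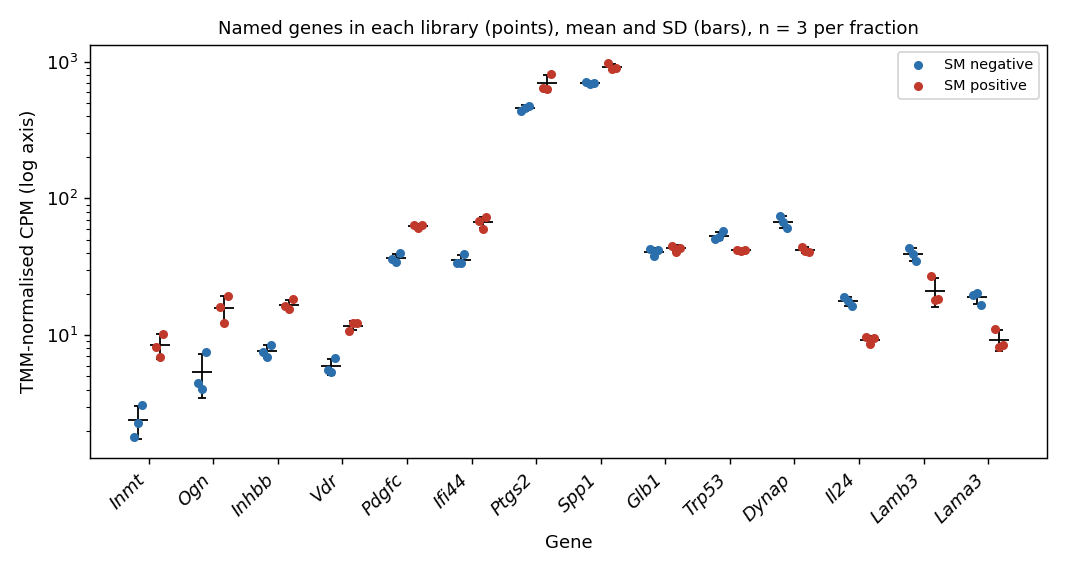
CPM of 14 named genes (horizontal axis) on a log axis, with 1 point per library in blue for SM negative and red for SM positive; black bars give the mean and SD of 3 libraries. The fractions' points do not overlap for any of these genes except Glb1.

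Of the 26 lists tested, 10 were called by camera with the preset correlation, 7 higher and 3 lower in SM positive cells. None of the 10 held when the correlation between genes was estimated from the data, and fry called 1, the mesenchymal and matrix list (adjusted p = 0.046). The estimate was 0.83 for ribosomal protein, 0.785 for DNA replication, 0.68 for cholesterol and 0.531 for glycolysis and hypoxia genes. It was 0.436 for oxidative phosphorylation, 0.351 for interferon, 0.128 for lysosome and 0.061 for drug transport genes. Only the mesenchymal and matrix list (0.017) and the NRF2 list (0.013) came close to the preset 0.01. Where the estimate was far above the preset, as for the interferon list, the p with the preset may be too small. The estimated run takes its degrees of freedom from the few libraries, so it could hardly call any list. A lost call there does not by itself show that correlation between genes made the call. With the replicate block, camera called 9 of the 10 and fry none.

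Interferon-response genes were the list with the smallest p (camera adjusted p = 3.99e-17; adjusted p = 0.68 with an estimated correlation). Of 63 tested members, 57 had a positive log2 change, with a median of 0.31. Past the threshold over all genes, 9 rose and none fell; adjusted over the list alone, 39 rose and 1, the chemokine gene Ccl5, fell. With the replicate block, 42 rose and Ccl5 fell. Ifi44, an interferon-induced gene (chromosome 3, 151730922 to 151749960, minus strand), rose from 35.6 ± 3.13 to 67.1 ± 6.49 CPM (log2 change 0.92 ± 0.0885 SE, adjusted p = 0.002). Ddx60, a helicase linked to antiviral sensing, rose from 29.4 ± 1.46 to 41.3 ± 0.546 CPM (log2 change 0.49 ± 0.0682 SE, adjusted p = 0.00962). Camera called the list with each of the 6 libraries left out in turn, at adjusted p = 3.51e-11 or less. Of 25 antigen presentation genes, none passed the threshold over all genes or adjusted over the list alone, and with the block Psmb8, Psmb9, Tap1 and H2-T23 rose and H2-Q7 fell. That list was not called (adjusted p = 0.125). It was called higher without SM negative replicate 1 (0.046) or SM positive replicate 3 (0.0482), with no filter (0.0471), and with the block and pair 3 left out (0.0375). It was also called with the length trend removed (0.0466, and 0.0209 with the block) and with the block and the GC trend removed (0.0358).

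Mesenchymal and matrix genes were also higher as a list (camera adjusted p = 1.39e-05; adjusted p = 0.295 with an estimated correlation). Of 33 members, 4 rose and none fell; adjusted over the list alone, 5 rose, and with the replicate block 15 rose. The 4 were Spp1, Col6a1 and, named after their values were seen, Thbs1 and Col5a1. Spp1, the secreted phosphoprotein osteopontin, rose from 697.9 ± 8.58 to 916.9 ± 46.2 CPM (log2 change 0.39 ± 0.0537 SE, adjusted p = 0.00962). Gm42793 overlaps Spp1 on the same strand, and 14.3% of its 31-base stretches occur in other genes. Col6a1, a collagen VI chain, rose 1.4-fold, Col5a1, a collagen V chain, 1.65-fold, and Thbs1, the adhesive glycoprotein thrombospondin 1, 1.66-fold. The fibroblast and pericyte list had a median log2 change of 0.23 and was not called (adjusted p = 0.377). Epithelial genes were not called (adjusted p = 0.348), and none of 33 members passed the threshold over all genes or adjusted over the list alone; with the block, Krt19, Epcam and Cldn4 fell.

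The secretory phenotype list, made of cytokines, chemokines, proteases and growth factors released by senescent cells, was not called (camera adjusted p = 0.581). Its median log2 change was 0.03 and its mean -0.02, so these differ in sign. Of 45 tested members, 4 rose and none fell; adjusted over the list alone, 6 rose and 2, Cxcl16 and Ccl5, fell, and with the replicate block 13 rose and 4, Cxcl16, Ccl5, Mmp9 and Vegfc, fell. The 4 were Spp1, Ptgs2 and, named after their values were seen, Tnfrsf1b and Tgfb2. Ptgs2, the inducible prostaglandin synthase, rose from 457.2 ± 20.7 to 695.1 ± 97.4 CPM (log2 change 0.60 ± 0.0895 SE, adjusted p = 0.0148). The NF-κB target list was not called (adjusted p = 0.635), with Ptgs2 and Lcn2 higher among 33 members, over all genes and adjusted over the list alone, and 6 higher and 4, Tnip1, Traf1, Vcam1 and Nfkbib, lower with the block. Its median log2 change was -0.005 and its mean 0.036. Lcn2, the secreted iron-siderophore binder lipocalin 2, rose 1.81-fold to 9.67 ± 1.52 CPM.

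The list of axitinib targets and angiogenic factors was not called (camera adjusted p = 0.105), with 2 of 22 members higher. Pdgfc, a ligand of PDGF receptors (chromosome 3, 81036416 to 81214040, plus strand), rose from 36.6 ± 2.95 to 63.2 ± 1.99 CPM (log2 change 0.79 ± 0.0717 SE, adjusted p = 0.00159). Nrp1, a co-receptor for VEGF and semaphorins that contains Mir1903 on the same strand, rose from 8.87 ± 0.474 to 14.4 ± 3.04 CPM (log2 change 0.70 ± 0.145 SE, adjusted p = 0.0461). Adjusted over the list alone, Efnb2 and Kitl rose too, and with the replicate block 7 members rose and 2, Vegfb and Vegfc, fell. The Nrp1 call ended with each single library left out (adjusted p from 0.052 to 0.163), with library totals (0.0524), the filter of more than 1 CPM (0.0505), limma-voom (0.0769) and the fit without robust estimation (0.0593). The list was called higher without SM positive replicate 3 (0.0381), with no filter (0.0196) and with the filter of more than 1 CPM (0.0464). Drug transport and metabolism genes were called higher (camera adjusted p = 0.0449; adjusted p = 0.715 with an estimated correlation). Of 19 members, 2 rose, and 3 rose and 1, the efflux pump gene Abcb1b, fell when adjusted over the list alone; with the replicate block 6 rose and 2, Abcb1b and Abcc4, fell. Aldh3a1, an aldehyde dehydrogenase, rose 1.89-fold to 7.98 ± 0.601 CPM, and Ahr, a ligand-activated transcription factor that induces drug-metabolising enzymes, rose 1.5-fold to 34.1 ± 2.24 CPM. This call ended with the replicate block (adjusted p = 0.153, in a range of 0.00858 to 0.368 over the other settings with the preset correlation). It also ended with library totals (0.0507), without SM negative replicate 1 or 2 (0.0613 and 0.0857), and without SM positive replicate 1 or 3 (0.149 and 0.0927).

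Cholesterol synthesis genes were higher as a list (camera adjusted p = 0.000105; adjusted p = 0.741 with an estimated correlation), with 24 of 25 members positive and a median log2 change of 0.17. Of these, Insig1, a sterol-sensing regulator of the pathway, passed the threshold (526.7 ± 12.9 to 625.8 ± 11.3 CPM, log2 change 0.25 ± 0.0491 SE, adjusted p = 0.0388). Adjusted over the list alone, 2 members rose, Insig1 among them, and with the replicate block 16 members rose and none fell. Without SM positive replicate 2 the list's adjusted p was 0.0857. Glycolysis and hypoxia genes were called higher (adjusted p = 0.00335; adjusted p = 0.792 with an estimated correlation). Car9, a hypoxia-induced carbonic anhydrase, rose from 97.0 ± 8.61 to 139 ± 13.2 CPM, the 1 member of 40 past the threshold; adjusted over the list alone, Car9 and Pfkfb3 rose, and with the block 20 rose and none fell. The list's adjusted p was 0.101 without SM negative replicate 1 and 0.394 without SM positive replicate 2.

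Lysosome genes, the list closest to the sort, were called higher by a small amount (camera adjusted p = 0.00169; adjusted p = 0.715 with an estimated correlation). Of 59 members, 46 had a positive log2 change, with a median of 0.06, and none passed the threshold over all genes or adjusted over the list alone. With the replicate block, 14 rose and 1, the protease gene Ctsl, fell. The NRF2 and oxidative stress list was called higher (adjusted p = 0.0232; adjusted p = 0.68 with an estimated correlation). Of its 36 members Aldh3a1 rose; adjusted over the list alone, Mgst1, Nfe2l2, Cat and Osgin1 rose too, and with the block 6 rose and 2, Sqstm1 and Gsta1, fell. The call ended without SM negative replicate 3 (0.0773), without SM positive replicate 2 (0.182), and with the block and pair 2 left out (0.172).

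Of the lists lower in SM positive cells, ribosomal protein genes had the smallest p (camera adjusted p = 6.75e-13; adjusted p = 0.715 with an estimated correlation). Of 59 members, 58 had a negative log2 change, with a median of -0.14. None passed the threshold over all genes or adjusted over the list alone, and 34 fell with the replicate block. Rpl23a, a ribosomal protein gene outside the list that was chosen after its values were seen, did pass. It fell from 931 ± 69.5 to 750 ± 18.3 CPM (log2 change -0.312, adjusted p = 0.0388), and 52.3% of its 31-base stretches occur in other genes. DNA replication and S phase genes were called lower (adjusted p = 0.00157; adjusted p = 0.792 with an estimated correlation). Of 59 members, 51 were negative with a median of -0.10, and none passed over all genes or adjusted over the list alone. With the block, 18 fell and 2, Rrm2 and Ccne2, rose. This call ended without SM negative replicate 1 or 2 (0.0613 and 0.131) and without SM positive replicate 3 (0.808). Nuclear-encoded oxidative phosphorylation genes were called lower (adjusted p = 0.00435; adjusted p = 0.792 with an estimated correlation), with none of 53 past the threshold over all genes or adjusted over the list alone, and 3, Ndufb9, Ndufa5 and Atp5a1, lower with the block. That call ended without SM negative replicate 1 (0.29), without SM positive replicate 3 (0.231), with no filter (0.113), and with the block and pair 1 or 3 left out (0.0596 and 0.0725). After a trend of the fold changes with transcript length was removed, the oxidative phosphorylation list (adjusted p = 0.308) and the drug transport list (0.0988) were no longer called.

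**Figure D3:**
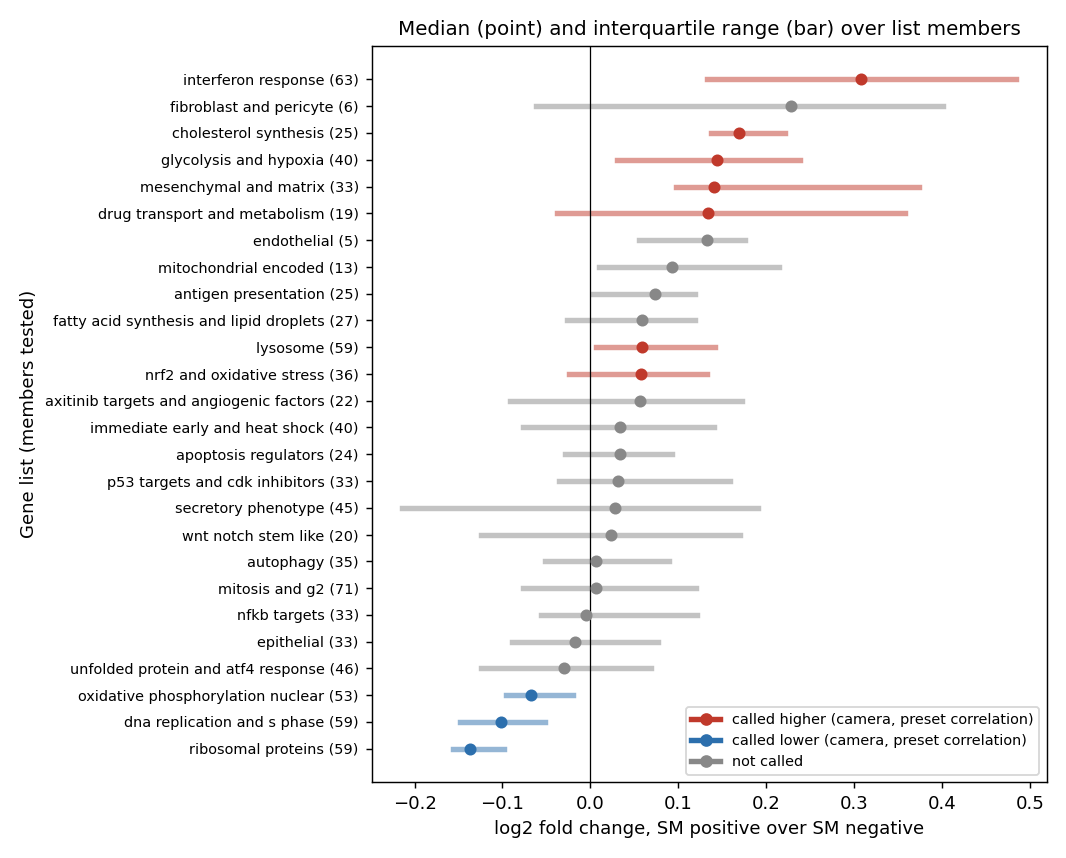
Median log2 fold change, SM positive over SM negative (points), and interquartile range over members (bars) of the 26 tested gene lists, with the number of members tested in brackets. Red and blue lists were called higher and lower by camera with the preset correlation of 0.01; the interferon list has a median of 0.31 and the ribosomal protein list of -0.14.

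Mitosis and G2 genes did not move as a list (camera adjusted p = 0.467), and none of 71 members passed the threshold over all genes or adjusted over the list alone; with the replicate block 15 rose and 7 fell. Without SM negative replicate 1 or SM positive replicate 3 that list was called higher (0.0168 and 0.00113), as it was with the block and pair 3 left out (0.0176). Of 33 p53 targets and inhibitors of cyclin-dependent kinases, Cdkn2c, which encodes p18, rose from 102 ± 2.77 to 125.7 ± 7.57 CPM (log2 change 0.30 ± 0.0601 SE, adjusted p = 0.0404). It was also the 1 member past the threshold adjusted over the list alone, and with the block 7 rose and 3, Bax, Plk2 and Gadd45a, fell. The p53 list was not called (adjusted p = 0.34). The autophagy, unfolded protein response, apoptosis, fatty acid and lipid droplet, mitochondrially encoded, immediate early and heat shock, and Wnt, Notch and stem-like lists were not called either, with adjusted p = 0.703, 0.267, 0.34, 0.34, 0.473, 0.703 and 0.581. No member of these 7 lists passed the threshold over all genes. Adjusted over the list alone, Bmf and Bcl2 rose and Bax fell among apoptosis genes, Lpin1 and Acsl4 rose among fatty acid genes, Notch2 rose among stem-like genes, and none passed in the other 4. With the replicate block, 1 autophagy gene (Atg5) rose and 3 (Sqstm1, Pik3c3 and Atg9b) fell, 10 unfolded protein response genes fell and 4 (Pdia6, Sel1l, Dnajc3 and Nupr1) rose, and 7 immediate early and heat shock genes rose and 4 (Myc, Klf10, Junb and Hspe1) fell. In that fit Apaf1, Cflar, Bmf, Bcl2, Lpin1, Scd2, Acsl4, Acsl3, Hilpda, Sox9, Id2, Notch2 and Cd24a rose and Bax, Bok, Acsl5, Fabp5, Plin2 and Procr fell in the apoptosis, fatty acid and stem-like lists, and no mitochondrially encoded gene passed.

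In the lists written for host cells that could have been carried over from the lesions, no tested member passed the test over all genes, and some passed with the replicate block. Only 2 members each of the macrophage, lymphocyte, and erythroid and platelet lists were expressed enough to be tested. Cd14 stood at 7.81 ± 1.3 CPM in SM positive and 8.22 ± 1.1 in SM negative cells, and Cd68 at 4.9 ± 0.721 and 6.74 ± 1.1 (adjusted p = 0.233, and 0.0148 with the replicate block); Cd68 also passed as lower adjusted over the list alone. Trac stood at 4.45 ± 0.457 and 4.41 ± 0.596 CPM, Lck at 1.47 ± 0.447 and 1.65 ± 0.101, Ppbp at 0.935 ± 0.293 and 1.16 ± 0.15, and Itga2b at 0.569 ± 0.0857 and 0.657 ± 0.265. The fibroblast and pericyte list (6 members, median log2 change 0.23, adjusted p = 0.377) and the endothelial list (5 members, median 0.13, adjusted p = 0.635) were not called, and none of their members passed over all genes or adjusted over the list alone. With the block Pdgfra rose in the fibroblast list (log2 change 0.50, adjusted p = 0.0423). Their most abundant members, which mammary tumour cells can also express, were Postn (307 ± 9.13 and 290 ± 17.5 CPM), Gsn (306 ± 16.2 and 330 ± 21), Eng (75.1 ± 2.93 and 68.5 ± 1.88, adjusted p = 0.34, and 0.0426 with the block) and Egfl7 (5.57 ± 0.499 and 5.34 ± 0.839).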

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

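The fits with 1 pair of libraries left out and the removal of length and GC trends were chosen after the data had been seen; the other alternatives were planned. Against 190 genes (160 higher, 30 lower), the replicate block gave 1982 (1196 and 786), and with pair 1, 2 or 3 left out 705 (506 and 199), 1793 (1029 and 764) and 886 (637 and 249). With the block and the length trend removed there were 1999 (1062 and 937), and with the block and the GC trend removed 2176 (1221 and 955). No filter gave 663 (494 and 169), DESeq2 334 (268 and 66), a change of at least 1 on the log2 scale 34 (19 and 15), and an adjusted p under 0.01 33 (28 and 5). Leaving out 1 library gave 25 to 123 genes (21 to 102 higher, 4 to 26 lower); these fits have fewer samples, and for the other settings the cause was not tested. RLE size factors gave 189, library totals 175, a filter of more than 1 CPM 172, limma-voom 137 and the fit without robust estimation 151. The share of higher genes was 84.2% in the main test and 82.9% to 84.1% under the other scalings, and 60.3% with the block.

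Against 10 called lists, the estimated correlation left 0 and fry 1, the block 9, and the other settings 7 to 11, including 7 to 10 with 1 library left out. None of the 10 called lists and none of the 33 called named genes reversed direction in the fits run on them; single genes were not followed with a pair left out or a trend removed. The block changed the calls of Mki67, Cd68 and Eng, and of no other gene that the rule for named genes took. The drug transport list lost its call with the block, and no other list call changed with it. With no filter the axitinib target (0.0196), antigen presentation and fatty acid lists (both 0.0471) were called higher, the axitinib target list also with the filter of more than 1 CPM (0.0464), and the oxidative phosphorylation (0.113) and drug transport (0.368) calls ended; the cause was not tested. Of the named genes, limma-voom ended the calls of Trp53 (0.0509), Dock4 (0.0514), Spata7 (0.0561), Cdkn2c (0.0572) and Nrp1 (0.0769), and the fit without robust estimation those of Spata7 (0.0512), Cdkn2c (0.0527) and Nrp1 (0.0593). With the block, the drug transport list was also not called with pair 1, 2 or 3 left out (0.279, 0.135 and 0.333). Depth limits Il6, while Cdkn2a and Cdkn2b had no count in any library. Of the smallest changes simulated with a pair effect, 4% were recovered (16% with the block). That simulation had more spread than these data, so it does not give the sensitivity of the real fits.

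Over the 10 splits of the 6 libraries into 3 and 3, the real one gave 190 genes and the highest other 1, and 1 of the 10 splits gave as many. Over the 4 splits that part all 3 pairs, the blocked fit gave 1982 genes for the real one and 0 for the highest other, and 1 of the 4 gave as many. For called lists, 2 of the 10 splits gave as many as the real one, with 10 lists in each, while the other splits that part all 3 pairs gave 3, 7 and 0. The splits are too few for a share under 0.05.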

Other observations

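The genes of the opening 2 paragraphs, the 2-cell gene list, and the tests of a length effect on single lists were chosen after the results were seen; the tests of the 2-cell list and of the other patterns were set before their outcome was known. Genes of the TGF-β family and of the Ltbp family, named for latent TGF-β binding, were looked at singly, with no test of them as a group. Tgfb3 rose from 37.3 ± 3.44 to 56.4 ± 4.58 CPM (log2 change 0.59 ± 0.0859 SE, edgeR adjusted p = 0.0119), and Tgfb2 rose 1.51-fold (adjusted p = 0.0485). Ltbp3, which holds latent TGF-β in the matrix, rose from 370 ± 16.5 to 504 ± 9.59 CPM (adjusted p = 0.00489), and Ltbp2 from 76.3 ± 2.37 to 95.4 ± 4.01 CPM (adjusted p = 0.0267). Ltbp1 stood at 399 ± 15.9 and 337 ± 15 CPM (adjusted p = 0.064, and 0.00019 with the replicate block), while Tgfb1 (log2 change -0.21, adjusted p = 0.503) and Ltbp4 (adjusted p = 0.637) did not pass in either fit. The matrix crosslinking enzymes Loxl3 and Tgm2 rose 1.72-fold and 1.36-fold, and Mgp, a matrix inhibitor of calcification, 1.81-fold.

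Other single genes stood out. Cp, which encodes the copper-carrying ferroxidase ceruloplasmin, rose from 285 ± 41.7 to 524 ± 49.3 CPM (adjusted p = 0.00913). Cdon, a hedgehog co-receptor, rose 1.72-fold, Tns4, a focal adhesion protein, 1.52-fold, and the kinase gene Sgk1 1.43-fold. Arg1, the arginase often used as a macrophage marker, rose from 1.89 ± 0.218 to 5.94 ± 0.689 CPM (adjusted p = 0.0022), while the macrophage gene Cd68 stood at 4.9 ± 0.721 in SM positive and 6.74 ± 1.1 CPM in SM negative cells. Hsd11b2, which inactivates glucocorticoids, rose 2.99-fold from a low level, and the homeobox gene Rhox5 was 2.7-fold lower. Gm48512 had 0 counts in all SM positive libraries and 13 to 29 in SM negative ones, at least 7.38-fold lower against a limit of 3 counts per library, and the pseudogene Rps12-ps4, which shares 94% of its sequence stretches, had 0 against 11 to 13, at least 4.02-fold lower.

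Genes of the embryonic 2-cell stage, a state that a few cells of some cultures enter, were lower in SM positive cells: of 21 tested genes, 20 had a negative log2 change with a median of -1.56, and 5 fell in the main test and 17 with the replicate block. Reads moved between near-identical copies would leave a family's sum level, but the Zscan4 family summed over 9 genes stood at 1.40 ± 0.186 against 4.94 ± 0.892 CPM (log2 change -1.81 ± 0.198 SE, adjusted p = 0.00272). More background reads in SM negative libraries would lower other barely expressed genes too, but 738 genes of the same level had a median of -0.0678; the share of counts in genes under 1 CPM did differ, at 0.169% ± 0.00688 and 0.190% ± 0.00699. The 12 members not among the genes noticed at the start had a median of -1.42. Of 10000 random lists matched on level, a share of at most 1e-04 was as low. This is the smallest value the test could give (permutation p = 1e-04, for genes drawn as if independent). None of these 12 passed the main test and 8 fell with the block. They include Zscan4-ps2, Usp17la and Usp17le, whose relatives Zscan4b, Zscan4f, Zscan4-ps3 and Usp17lc were among the genes noticed. These 12 are therefore not an independent check of the pattern. Fewer 2-cell-like cells in the high-signal fraction may explain the lower 2-cell genes, as a hypothesis that was not itself tested and rests on low counts (24 to 37 against 83 to 126 Zscan4 counts per library).

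Log2 change rose with transcript length across genes (Spearman rho 0.21 over 14018 genes, which are not independent replicates), and the ribosomal protein and oxidative phosphorylation lists (median lengths 1120 and 1232 bases) were called lower, while the short mitochondrially encoded (784 bases) and endothelial (1865 bases) lists had positive medians and were not called. Removing a GC trend kept 95.8% of the ribosomal protein median (camera adjusted p = 1.25e-12). The rho with GC was -0.099, and -0.114 over genes above 1 CPM. This argues against GC content as the whole cause for that list. Removing the length trend kept 69.1% of the median (from -0.137 to -0.0945, camera adjusted p = 5e-09 with the preset correlation). Each gene's length was that of its longest annotated transcript, which need not be the one expressed. The trend may thus be removed incompletely, and length as the whole cause for that list stays open. The oxidative phosphorylation call ended (adjusted p = 0.308) and its median shrank from -0.065 (interquartile range -0.094 to -0.020) to -0.030 (-0.057 to -0.001), so a length bias may account for that list. The drug transport call ended too (adjusted p from 0.0449 to 0.0988), with a median of 0.128 (interquartile range -0.038 to 0.358) before and 0.089 (-0.065 to 0.368) after. Length thus stays open for that list. The other 8 calls held with the trend removed, with medians going from 0.309 to 0.322 for interferon, 0.161 to 0.158 for cholesterol and -0.110 to -0.125 for DNA replication genes. This argues against length as the cause for the interferon, cholesterol and DNA replication lists, although the trend is there. Its rho missed the bound of 0.1 set beforehand for ruling length out, so length stays open for the list calls as a whole. The rho also reached the bound set beforehand for length as the cause, but the other conditions set with that bound were not met. A biological difference between the fractions was not tested.

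The predicted zinc finger gene 2210418O10Rik rose 14.7-fold, from 0.757 ± 0.509 to 10.8 ± 0.393 CPM (adjusted p = 0.00101). All of its 31-base stretches (100%) occur in other genes, and 52 genes share at least 100 of them. If reads were split differently within the family, these genes would lose what it gained: they lost 71.2% of it, from 103.3 ± 14.6 to 96.2 ± 10.4 CPM, but the loss was 7.57, 13.3 and 0.558 CPM in pairs 1, 2 and 3 against gains of 9.95, 9.31 and 10.9. Gm14296, chosen after the values were seen, alone fell from 21.1 ± 1.36 to 12.6 ± 1.31 CPM (adjusted p = 0.00914), by 9.84, 8.57 and 7.15 CPM in the 3 pairs. Reassigned reads may thus explain this gene, which cannot be told apart from a change in transcription because the sharing genes together lost little in pair 3.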
